A study of Homo sapiens with 6 samples.

How the data were processed

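The series measured polyadenylated RNA in HEK293T cells, an established human embryonic kidney line, that are deleted for GLO1 per the labels, the glyoxalase which starts the main route of methylglyoxal (MGO) clearance. Per the labels' protocols, cells received 60 µM MGO for 4 h (group MGO, 3 libraries) or no treatment (group Control, 3 libraries). The library names of the MGO group hold a number that differs from this dose, and its meaning is not given in the sources used here. Per the same protocols, 500 ng of total RNA with an integrity number of 10 was polyA selected and made into stranded libraries with 8 PCR cycles, then read as pairs of 100 bp reads on an Illumina NovaSeq. The submitters gave a mean of 204 M read pairs per library, 0.09 to 0.32% ribosomal reads and a mean of 92% of bases in mRNA.

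The deposited values are raw counts per gene. Per the submitters' processing notes, FastQC 0.12.0, Trim Galore 0.6.10, STAR 2.7.0a, SAMtools 1.19.2, featureCounts 2.0.6, DESeq2 1.42.0 and the genome build hg38 were used. The gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Values of genes with close copies (ribosomal protein genes and their pseudogenes, histone genes, CHMP4BP1, HADHAP1, TATDN2P2) and of overlapping or antisense genes are therefore uncertain. Genes that most cells use were also at or near 0, such as IARS1, VARS1, FBL and LDHA with 3, 2, 7 and 8 counts over all 6 libraries, so a count of 0 is not read as absent expression. The table held 63643 rows, 41042 under a gene symbol and 22601 under an Ensembl identifier, and 56845 rows matched a gene of GENCODE release 29, which gave coordinates on GRCh38 (the same assembly as hg38), gene span, GC content and transcript length. Transcript length is the median over a gene's basic transcripts, coding ones for coding genes.

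Total counts per library were 128270160, 138680220 and 138554431 in MGO replicates 1 to 3 and 117427883, 157639431 and 146453569 in Control replicates 1 to 3. All pairs of libraries within a group differed by more than sampling noise (chi-square per degree of freedom of 3.77 or above), so each was counted as 1 replicate. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicate numbers were treated as names.

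Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr by group, TMM scaling, and the quasi-likelihood test of MGO against Control, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) of log2 fold changes were computed as the absolute log2 fold change divided by the square root of F. CPM values are counts scaled by the TMM-scaled library size, given as mean ± SD (n = 3). Without spike-in RNA the absolute scale is unknown, and all changes are relative to this scaling. The 27 gene lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, adjusted over the lists), with camera using an estimated correlation, and with fry. Fry values are those of its directional test unless named as mixed. Because fold changes followed transcript length, each list's median was also set beside 10000 random lists drawn from genes in the same of 20 transcript length bins, 3 gene span bins and the same expression class. These matched lists describe the libraries and are not a test between conditions. On simulated counts with 200 changed genes among 22477 tested, the same steps recovered 8% of genes changed 1.25-fold, 42% at 1.5-fold, 82% at 2-fold and 98% at 4-fold. Far fewer genes changed there than were called in the data, so these shares do not give the recovery in the data.

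The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the stress-response genes ATF4, DDIT3, ATF3, ASNS, CHAC1, TRIB3, SESN2, PPP1R15A and DDIT4, and GLO1, whatever their values. It added the 10 largest rises and 10 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and no overlap between the groups. From each list it took the 2 largest rises and 2 largest falls past the threshold. Some genes that the rule takes are not reported here. The alternatives were other scalings (RLE size factors, library size alone, upper quartile), other filters on low counts, DESeq2 1.42.0, limma-voom, robust dispersions, a test against a 1.2-fold change, a replicate block and leaving out each library. Removal of the trend of each library on transcript length, gene span and GC content was added after the data were seen. The rule on symbols for nuclear respiratory chain subunits also matched pseudogenes such as ATP5MC1P4 and UQCRFS1P1, which stayed in the list.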

Results

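RNA was profiled in HEK293T cells labelled as deleted for GLO1 to ask whether exposure to MGO, a reactive by-product of glycolysis, changes transcripts of the integrated stress response (ISR). This pathway lowers general translation and raises the transcription factor ATF4. The comparison sets 3 libraries from cells given 60 µM MGO for 4 h against 3 from untreated cells. Total counts lay between 128270160 and 138680220 in MGO and between 117427883 and 157639431 in Control libraries. Of the 63643 genes in the table, 21558 had no count in any library and 23109 were tested.

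GLO1 (chromosome 6, 38675925 to 38703141) had counts in every library, at 101.8 ± 4.53 CPM in MGO and 37.27 ± 0.885 in Control (log2 fold change 1.45, SE 0.06, edgeR adjusted p = 5.6e-10). The labels give the deletion for all samples and do not say which part of the gene is missing, so these counts check neither the deletion nor the group labels.

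Among genes with a symbol and a mean of at least 1 CPM, immediate early genes showed the largest rises after MGO. FOS, a subunit of the AP-1 transcription factor, rose from 3.849 ± 0.311 to 500.5 ± 48.0 CPM, and EGR1, a growth-factor-induced zinc finger factor, rose from 26.02 ± 3.43 to 1559 ± 138 CPM. ATF4, DDIT3, ATF3 and PPP1R15A also rose, while the ATF4 target genes ASNS, CHAC1 and SLC7A11 fell. In all, 8964 genes rose and 9362 fell at an edgeR adjusted p under 0.05, which is 79.3% of the genes tested. With a log2 fold change of at least 1 in size, 4829 rose and 5971 fell. The 3 MGO libraries did not overlap the 3 Control libraries for 18831 genes (81.5%, where chance gives 10%). Scaling by library size alone gave 5673 raised and 12885 lowered genes, so raised genes were 30.6% of the calls in place of 48.9%, and it moved the median of all genes by −0.52 on the log2 scale. Upper quartile scaling moved that median by 0.17.

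Among ISR regulators and stress targets, 12 of 23 tested genes rose, 8 fell and 3 did not pass the threshold. Adjusted over the list alone, 12 rose and 9 fell. PPP1R15A (chromosome 19, 48872392 to 48876057), which encodes the GADD34 subunit that directs dephosphorylation of eIF2α, had the largest rise, from 50.46 ± 0.548 to 1068 ± 41.4 CPM (log2 fold change 4.40, SE 0.07, adjusted p = 2.92e-12). ATF3 (chromosome 1, 212565334 to 212620777) rose by 4.24 (SE 0.08, adjusted p = 3.94e-12). DDIT3 (chromosome 12, 57516588 to 57521737), which encodes the pro-apoptotic factor CHOP, rose from 10.05 ± 0.492 to 114.9 ± 3.20 CPM (log2 fold change 3.52, SE 0.07). ATF4 (chromosome 22, 39519695 to 39522685) rose from 383.1 ± 10.5 to 2303 ± 59.1 CPM (log2 fold change 2.59, SE 0.06, adjusted p = 2.06e-11). DDIT4, an inhibitor of mTORC1 signalling, rose by 1.26 (SE 0.09) and the pseudokinase gene TRIB3 by 1.09 (SE 0.09).

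The members of this list that fell included SLC7A11 (chromosome 4, 138164097 to 138242349), the cystine transporter, from 20.08 ± 2.86 to 1.938 ± 0.221 CPM (log2 fold change −3.37, SE 0.12, adjusted p = 1.99e-10). CHAC1 (chromosome 15, 40952962 to 40956519), a glutathione-degrading enzyme, had a log2 fold change of −2.28 (SE 0.16), from 8.438 ± 1.44 to 1.731 ± 0.370 CPM. ASNS (chromosome 7, 97852118 to 97872542), asparagine synthetase, had one of −1.87 (SE 0.16), from 3.840 ± 0.180 to 1.051 ± 0.283 CPM. Its Control level was low beside the median of 62.6 CPM over the 20 tested genes of ATF4-driven amino acid synthesis and transport. Whether reads of ASNS were lost in counting was not tested, so its fall is uncertain. The transcripts of SLC7A11, CHAC1 and ASNS have 9645, 1425 and 1865 nt. SESN2 was listed at 0 in all 6 libraries. Genes that most cells use were also near 0, such as IARS1 and VARS1 with 3 and 2 counts in total, so this value is not read as absent expression. The list's median log2 fold change was 0.50 and camera gave an adjusted p = 0.00275, which was lost with an estimated correlation (adjusted p = 0.302) and with limma-voom (adjusted p = 0.168). Its median turned to −0.03 under library size alone, and it lay at the 81.3 percentile of lists matched on transcript length.

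**Figure D1:**
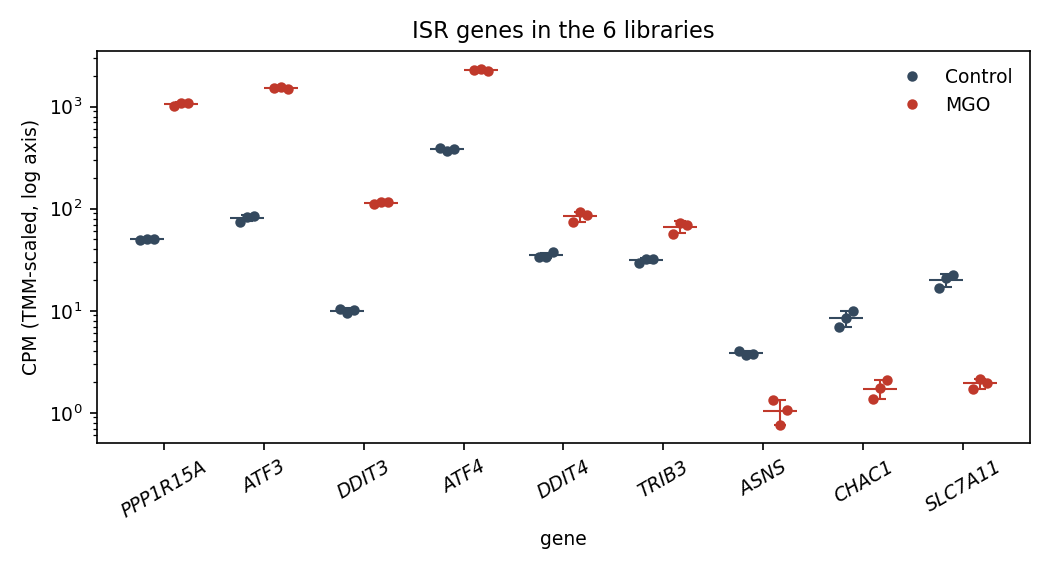
Normalised read counts (CPM, TMM-scaled, log axis) of 9 ISR genes, with each point 1 library and horizontal marks with bars the mean ± SD of the 3 libraries of a group. The 3 MGO libraries lie above the 3 Control libraries for PPP1R15A, ATF3, DDIT3, ATF4, DDIT4 and TRIB3, and below them for ASNS, CHAC1 and SLC7A11.

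Genes of ATF4-driven amino acid synthesis and transport divided in both directions, with 6 of 20 raised, 10 lowered and 4 not past the threshold (median −0.21, camera adjusted p = 0.966). SLC3A2, the heavy chain of several amino acid transporters, rose by 2.85 (SE 0.07) to 569 ± 22.3 CPM, and the cystathionine-cleaving enzyme gene CTH rose by 1.51 (SE 0.08). ALDH1L2, a mitochondrial folate enzyme, fell with a log2 fold change of −2.66 (SE 0.18). Of 18 cytosolic tRNA synthetase genes, 12 rose and 5 fell (camera adjusted p = 0.328), with FARSA at 1.22, KARS1 at 1.17, EPRS1 at −1.85 and LARS1 at −1.55, and the list's median of 0.32 turned to −0.20 under library size alone. Of 22 genes for endoplasmic reticulum (ER) chaperones and ER-associated degradation, 14 rose and 6 fell, with a median of 0.42 that turned to −0.10 under library size alone. DNAJB9, an ER co-chaperone, rose by 2.24 (SE 0.07) and XBP1 by 1.56 (SE 0.06), whereas SEL1L and EDEM1, which act in ER-associated degradation, changed by −2.51 and −1.21. The camera call for this list (adjusted p = 0.0397) ended with an estimated correlation (adjusted p = 0.343), and without Control replicate 2 (adjusted p = 0.0549) or Control replicate 3 (adjusted p = 0.0595). It also ended under library size alone (adjusted p = 0.235), with the 1 CPM filter (0.0743), with limma-voom (0.0559) and with a replicate block (0.0771). With the length trend removed it ended as well (0.456), and the list's median lay at the 51.9 percentile of matched lists.

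Of 34 immediate early and MAPK stress genes tested, 33 rose and none fell, with a median log2 fold change of 2.63 (camera adjusted p = 1.57e-37; adjusted p = 0.189 with an estimated correlation). SPRED2 did not pass the threshold, at 0.09; this exception and JUN below were named after their values were seen. EGR4 (chromosome 2, 73290929 to 73293705) had the largest log2 fold change, 8.30 (SE 0.28, adjusted p = 1.15e-10), from 8, 4 and 4 counts in the Control libraries to 1105, 1450 and 909 in the MGO libraries. FOS (chromosome 14, 75278774 to 75282230) rose by 7.02 (SE 0.11), FOSB by 6.38 (SE 0.13), EGR2 by 6.26 (SE 0.15), EGR1 by 5.90 (SE 0.12) and EGR3 by 5.16 (SE 0.13). JUN reached 3855 CPM in MGO from 343.7 in Control. MAFF, a small Maf transcription factor outside this list, rose by 5.56 (SE 0.09). Among genes with a symbol and a mean of at least 1 CPM, the other largest rises outside the list were those of RNF148 (4.84), and of the pseudogenes CHMP4BP1 (4.58) and HADHAP1 (4.58), for which reads shared with their parent genes were not tested. The median transcript length of the immediate early list was 2573 nt, and its median change exceeded all 10000 lists matched on length, of which the central 95% lay between −0.04 and 0.80.

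All 4 targets of the glucose-responsive factor MondoA rose, among them TXNIP, an arrestin-like brake on glucose uptake, from 25.25 ± 0.844 to 326.8 ± 3.30 CPM (log2 fold change 3.69, SE 0.07), and KLF10 (3.37, SE 0.07). The list's camera adjusted p was 5.56e-09, and adjusted p = 0.150 with an estimated correlation. Of 20 p53 targets, 12 rose and 8 fell, with GADD45A at 2.67, the pro-apoptotic gene BBC3 at 3.08, TP53INP1 at −1.41 and TIGAR at −1.21 (camera adjusted p = 0.00407; adjusted p = 0.302 with an estimated correlation, and 0.142 with limma-voom). Of 16 hypoxia targets, 9 rose and 2 fell (camera adjusted p = 0.00839; adjusted p = 0.249 with an estimated correlation), and the median of 0.24 turned to −0.29 under library size alone. The vasodilator peptide gene ADM rose by 3.53 (SE 0.07), ANKRD37 rose by 2.11 (SE 0.15) and ANGPTL4 had a change of −1.77 (SE 0.25). Among 15 NF-κB and inflammatory genes, 6 rose and 5 fell (median 0.34, or −0.19 under library size alone; camera adjusted p = 0.471), with NFKBIE at 1.92 and BIRC3 at −3.05. Among 17 interferon-stimulated genes, 4 rose and 9 fell (median −0.42, camera adjusted p = 0.59), with IRF7 at 1.48 and OAS3 at −1.55.

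**Figure D2:**
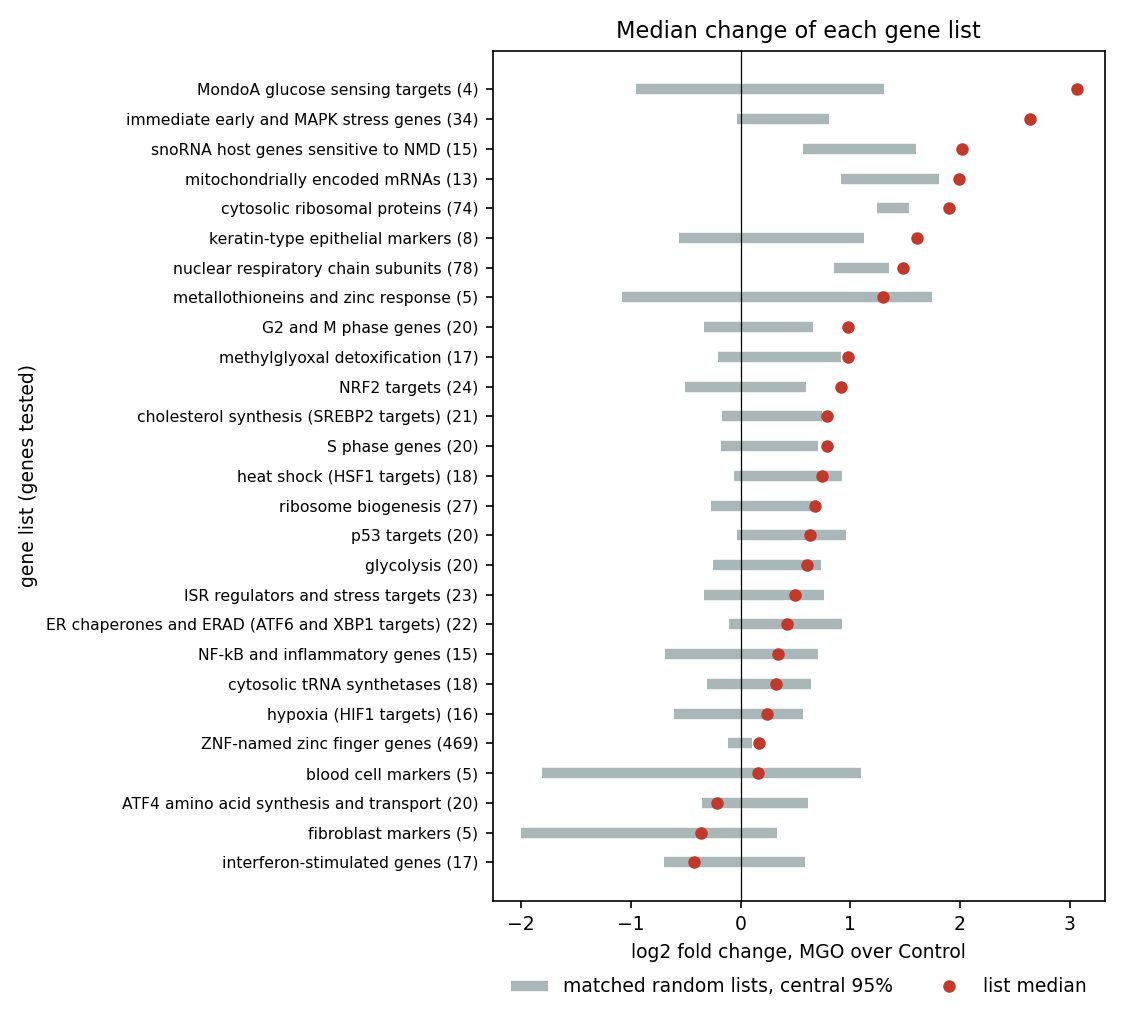
Median log2 fold change (MGO over Control) of each of the 27 gene lists, with the number of genes tested in parentheses and grey bars for the central 95% of 10000 random lists matched on transcript length, gene span and expression. The immediate early list (2.63) and the MondoA list (3.07) lie farthest to the right, and under library size alone the medians of the ISR, tRNA synthetase, ER, NF-κB, hypoxia, ZNF-named and blood cell lists change sign.

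All 74 cytosolic ribosomal protein genes tested rose, with a median of 1.90 (camera adjusted p = 1.16e-43; adjusted p = 0.302 with an estimated correlation). Their transcripts are short, with a median of 723 nt, and lists matched on length had a median of 1.41 with a central 95% from 1.24 to 1.53. The largest rises, of RPS10 (2.60) and RPS18 (2.47), came at 24.08 ± 2.57 and 0.156 ± 0.0692 CPM in MGO. All 15 small nucleolar RNA (snoRNA) host genes, whose transcripts are known to be degraded by nonsense-mediated decay (NMD), rose with a median of 2.02 (camera adjusted p = 2.56e-18; adjusted p = 0.150 with an estimated correlation). SNHG15 rose from 37.77 ± 1.55 to 555.3 ± 9.42 CPM (log2 fold change 3.88, SE 0.07) and EPB41L4A-AS1 by 3.31 (SE 0.07). The median transcript length of these host genes was 767 nt, and matched lists had a central 95% from 0.57 to 1.60. Of 27 ribosome biogenesis genes, 18 rose and 7 fell (median 0.68, camera adjusted p = 0.0084; adjusted p = 0.398 with an estimated correlation, and 0.0918 under library size alone), with NOP16 at 2.40, WDR74 at 1.97, UTP20 at −3.04 and POLR1A, the large subunit of RNA polymerase I, at −2.39. UTP20 and POLR1A have long transcripts, of 9025 and 9601.5 nt, whereas those of NOP16 and WDR74 have 981.5 and 1366 nt.

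All 13 mitochondrially encoded mRNAs rose, with a median of 1.99 (camera adjusted p = 8.07e-11, and adjusted p = 0.302 with an estimated correlation), and MT-ND2 had the largest rise (2.65, SE 0.10). These transcripts are short, with a median of 784 nt, and matched lists had a median of 1.43 with a central 95% from 0.92 to 1.81. Genes of the mitochondrial chromosome took 13.6 ± 1.07% of the counts in MGO and 5.42 ± 0.124% in Control libraries. Of 78 nuclear genes for respiratory chain subunits, 74 rose and 2 fell (median 1.48, camera adjusted p = 1.21e-22; adjusted p = 0.302 with an estimated correlation), among them COX8A at 2.04 and NDUFB11 at 1.99. Their median transcript length was 749.5 nt, and matched lists had a central 95% from 0.86 to 1.35.

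Of 17 genes that clear MGO and related aldehydes, 14 rose and 1 fell, with a median of 0.97 (camera adjusted p = 0.00275; adjusted p = 0.302 with an estimated correlation). AKR7A2, an aldo-keto reductase, rose by 1.45 (SE 0.08), as GLO1 did, and ALDH3A2 fell slightly (−0.29, SE 0.06), a call that ended under upper quartile scaling (adjusted p = 0.0944) and with the length trend removed. Of 20 glycolysis genes, 17 rose and 1 fell (camera adjusted p = 0.00162; adjusted p = 0.379 with an estimated correlation), with GAPDH at 1.67 (SE 0.07) and the glucose transporter gene SLC2A1 at 1.47 (SE 0.07). HK2, the member that fell (−0.65, SE 0.09), stood at 0.46 with the length trend removed. Of 24 targets of the oxidative stress factor NRF2, 14 rose and 7 fell (median 0.91, camera adjusted p = 0.0311; adjusted p = 0.302 with an estimated correlation, 0.0918 under library size alone, 0.0663 with the 1 CPM filter and 0.0559 with limma-voom). The ferritin light chain gene FTL rose by 1.81 (SE 0.07) and TXN by 1.59 (SE 0.07), while ABCC2 changed by −1.95 (SE 0.17). Of 18 heat shock genes, 11 rose and 5 fell (median 0.74, camera adjusted p = 0.0101; adjusted p = 0.379 with an estimated correlation, 0.0754 under library size alone and 0.140 with the length trend removed), with the co-chaperone genes BAG3 at 1.76 and DNAJB4 at 1.73. Of 21 cholesterol synthesis genes, 14 rose and 7 fell (camera adjusted p = 0.0676, or 0.0375 under upper quartile scaling, 0.0223 without a filter and 0.0442 without MGO replicate 3), with HSD17B7 at 1.43 and LSS at −1.78. Of 5 metallothionein and zinc response genes, 4 rose and 1 fell (camera adjusted p = 0.112), with MT2A at 1.61.

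Of 20 S phase genes, 15 rose and 3 fell (camera adjusted p = 0.00122; adjusted p = 0.302 with an estimated correlation), led by the replication licensing factor CDT1 at 2.32 and CCNE1 at 1.82. Of 20 G2 and M phase genes, 12 rose and 6 fell (camera adjusted p = 0.0118; adjusted p = 0.302 with an estimated correlation, 0.0844 under library size alone and 0.0559 with limma-voom). UBE2C (2.05) and AURKB (1.56) have transcripts of 705 and 1197 nt, and CENPF (−2.48) and CENPE (−2.47) of 5417.5 and 8260 nt. Among 469 ZNF-named zinc finger genes, 226 rose and 190 fell (227 and 191 adjusted over the list alone; camera adjusted p = 0.0512), and the median of 0.16 turned to −0.36 under library size alone. The list passed the threshold under RLE size factors (adjusted p = 0.0498), upper quartile scaling (0.0196), no filter (0.0416), DESeq2 (0.0368), fry (0.00374) and removal of the length trend (0.000774), and without MGO replicate 1 (0.0432), 2 (0.0377) or 3 (0.0174). It did not pass with an estimated correlation (0.623), library size alone (0.350), the 1 CPM filter (0.0663), limma-voom (0.172) or a replicate block (0.0833). Nor did it pass without Control replicate 1 (0.0990), 2 (0.0645) or 3 (0.0664). Robust dispersions do not enter the camera test, so their value (0.0512) repeats the main one. ZNF408 rose by 3.42 and ZNF256 by 3.34, and ZNF469 changed by −3.99. In the lists of other cell types, 7 of 8 keratin-type epithelial markers rose, including KRT17 (2.05) and KRT18 (1.87), and CDH1 fell (−1.56), with a camera adjusted p = 0.00389 and an adjusted p = 0.302 with an estimated correlation. KRT18 stood at 95.84 ± 3.31 CPM in Control libraries. Of 5 fibroblast markers 1 rose and 2 fell (camera adjusted p = 0.328), and of 5 blood cell markers 2 rose and 1 fell (camera adjusted p = 0.898; median 0.16, or −0.37 under library size alone). The raised blood cell markers, LYZ and SPI1, were at 0.286 ± 0.335 and 0.256 ± 0.112 CPM in MGO, and LYZ lost its call without MGO replicate 1 (adjusted p = 0.0739), SPI1 without MGO replicate 2 (0.134) or 3 (0.138), or Control replicate 1 (0.126) or 3 (0.0845). Apart from the ISR, ZNF-named and blood cell lists (1 raised and 1 lowered in the last), counts adjusted over the list alone equalled those over all genes. Fry's directional test asks whether a list moves 1 way, and not whether it moves more than other genes. It passed for every list except ATF4-driven amino acid synthesis and transport (adjusted p = 0.725) and the blood cell markers (0.242). Fry's mixed test, which asks whether members change in either direction, passed for every list. For the ATF4-driven and blood cell lists its adjusted p was 5.1e-06 and 0.00133. Lists that passed fry's directional test and not the main camera test were the tRNA synthetase (0.000705), NF-κB (0.00131) and interferon-stimulated (0.000145) lists. The cholesterol synthesis (0.00060), metallothionein (0.000527), fibroblast (0.00067) and ZNF-named lists did so too. No list passed camera with an estimated correlation (lowest adjusted p = 0.150).

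Among genes with a symbol and a mean of at least 1 CPM, the largest fall was that of XIST (chromosome X, 73820651 to 73852723), the long noncoding RNA of X inactivation, from 9562 ± 2410 to 159.1 ± 16.5 CPM (log2 fold change −5.91, SE 0.19, adjusted p = 8.29e-11). CD37, a tetraspanin gene, followed at −5.27 (SE 0.16), then FAM106A (−5.06), LECT2 (−4.79), BAHCC1 (−4.73), the cytoskeletal linker gene PLEC (−4.47), PKD1 (−4.47), the pseudogene TATDN2P2 (−4.33), C2orf16 (−4.32) and SOGA1 (−4.27). PLEC and PKD1 have transcripts of 14712.5 and 14136.5 nt.

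Fold changes followed transcript length across genes. Among 11510 coding genes above 1 log2 CPM, Spearman's rho between length and log2 fold change was −0.64, where genes are not independent replicates. With transcripts of up to 1 kb, 742 of 847 genes rose and 73 fell (median 1.31), and with transcripts over 8 kb, 22 of 471 rose and 431 fell (median −2.04). The slope was −0.83 per doubling of length and lay between −0.91 and −0.72 in the 9 pairs of 1 MGO and 1 Control library. The mean transcript length weighted by counts was 2140 ± 58.6 nt in MGO and 3293 ± 80.4 nt in Control libraries. With the trend on length, gene span and GC content removed, an alternative chosen after seeing the data, 2410 genes rose by at least 1 on the log2 scale in place of 4829 and 5163 fell by as much in place of 5971, with 21773 genes tested in place of 23109, and 1513 of 17406 calls took the opposite direction.

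**Figure D3:**
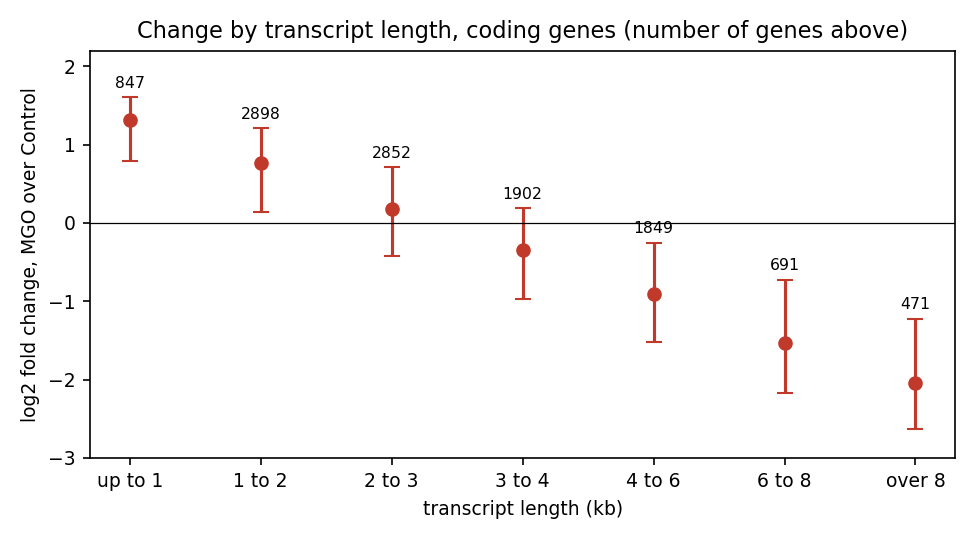
Log2 fold change (MGO over Control) of 11510 coding genes by transcript length in kb, with points for the median, bars from the lower to the upper quartile and the number of genes above each bar. The median lies at 1.31 for transcripts of up to 1 kb and at −2.04 for those over 8 kb.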

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

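The removal of the trend on transcript length, span and GC content was chosen after the data were seen; the other alternatives were planned. Counts of raised and lowered genes kept within 1.5 times of 8964 and 9362 under the other alternatives, except that library size alone gave 5673 raised, and 2227 raised by at least 1 on the log2 scale. A minimum of 1 CPM in 3 libraries gave 2992 and 3656 genes past that size, where fewer genes (14746) were tested, and removal of the length trend, with 21773 genes tested, gave 2410 raised and 5163 lowered past it, where the cause was not tested. DESeq2 called 8730 raised and 8984 lowered genes. Without 1 library each, 8684 to 9204 genes rose and 9062 to 9706 fell. Of 18326 calls, 15035 kept call and direction under library size alone, and 638 were called in the opposite direction. With the length trend removed, 12811 of 17406 kept both and 1513 were called in the opposite direction. Library size alone shifts all genes of a library alike, and under it list medians became −0.032 (ISR), −0.20 (tRNA synthetases), −0.10 (ER), −0.19 (NF-κB), −0.29 (hypoxia), −0.36 (ZNF-named) and −0.37 (blood cell markers). The ISR list (median 0.50) lost its call with an estimated correlation (adjusted p = 0.302) and with limma-voom (median 0.49, adjusted p = 0.168), and without 1 library each its median lay between 0.47 and 0.54. With the length trend removed, signs turned for ALDH3A2 (0.014), EGLN3 (0.31), HK2 (0.46), LCP1 (0.55) and the fibroblast list (0.041). The cause was not tested. Across all alternatives, 1777 comparisons of a named gene with its main result kept direction and side of the threshold, 17 lost the call and 4 turned. For lists 425 kept both, 34 lost the call, 18 gained one and 8 turned. The 425 include 27 with robust dispersions, which do not enter the camera test and could not differ. Of named genes, LYZ lost its call without MGO replicate 1 (0.96, adjusted p = 0.0739), IFI44L without MGO replicate 2 (adjusted p = 0.0506) or Control replicate 2 (0.0557), and SPI1 without MGO replicate 2 (0.134) or 3 (0.138), or Control replicate 1 (0.126) or 3 (0.0845). With a replicate block, 8869 genes rose and 9299 fell, and the ER list lost its call (adjusted p = 0.0771). Same-numbered MGO and Control libraries deviated with correlations of 0.03, −0.07 and 0.07, and differently numbered ones with −0.10 to 0.07. This check showed no strong pairing by number and cannot exclude a weak pairing. Simulated 2-fold changes were recovered in 82% of genes, with 200 of 22477 genes changed. In the data 79.3% of genes were called, which makes the adjusted threshold less strict, so the simulated shares do not carry over. Smaller changes can still be missed, at a rate that was not measured.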

Other observations

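Several gene groups that were not planned lists were chosen after their values were seen. Of 33 proteasome subunit genes, 32 rose and 1 fell (median 1.16), led by PSMA2 at 2.33, with a median transcript length of 1505 nt. PSMA2 stood at only 2.57 ± 0.325 CPM in Control and 12.9 ± 1.49 in MGO, and reads lost in counting were not tested. The next largest rise was that of PSMD8 (1.76), at 399 ± 9.84 CPM in Control. Of 45 replication-dependent histone genes, 39 rose and 2 fell (median 1.424), from polyA-selected RNA, although most histone mRNAs carry no polyA tail. Some varied widely between MGO libraries, such as H3C2 at 3.53 ± 2.33 and H1-4 at 4.51 ± 2.86 CPM. Small structural RNA took 0.0079, 0.049 and 0.022% of the counts in MGO replicates 1 to 3 and 0.0054, 0.011 and 0.0095% in Control replicates 1 to 3, and carry-over of RNA without polyA tails was not tested. All 3 GADD45 genes rose, with a median of 3.19; GADD45A is also in the p53 list. Of 94 snoRNA genes, 68 rose and 12 fell (median 1.60), and reads shared with their host genes were not tested.

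Of 39 genes of the protocadherin, FAT, CELSR and DCHS cadherin families, also chosen after their values were seen, 33 fell and 2 rose, with a median of −1.85 and a median transcript length of 4398 nt. Single long genes that fell included PRKDC, the DNA-dependent protein kinase, at −4.17 and SYNE2, a nuclear envelope linker, at −3.80.

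The scaling alternatives were planned. Their bounds and the other tests described here, with the removal of the length trend, were chosen after the results were seen. The first form of 2 of them left the matter undecided and was replaced. A bound of 1 in place of 0.5 was not passed by more than 2 standard errors for the snoRNA host genes, and medians after the length trend of −1.18 (SE 0.50) for the lowered and 1.01 (SE 0.46) for the raised ISR genes did not clear their bounds. A further test, the number of ISR genes on each side under other scalings, was replaced. The reason was that 1 factor per library moves all genes alike and could hardly end the split. Most other lists also passed the bound of its replacement. The replacements were written with those values known and carry less weight. Across the 10 splits of the 6 libraries into 3 and 3, the real one gave 18326 changed genes, 10800 of them at least 2-fold, and was the 1 split with as many. In the other 9 splits edgeR and limma-voom called 0 genes after adjustment, with at most 74 at an unadjusted p under 0.05 in edgeR. Each of these 9 splits put MGO and Control libraries on both sides, which widens the spread within a side. Few calls were therefore likely in advance, and these counts decide nothing on chance. The splits are too few for a share under 0.05.

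The first pattern is the fall of fold change with transcript length. GC content as the whole cause is argued against, since the slope per doubling of length stayed at −0.81 with GC in the model. Gene span alone is argued against by a slope on transcript length of −0.64 with span in the model, and transcript length alone by a slope on span of −0.15 among genes with 1 basic transcript. Among 1145 noncoding genes the bounds set for these tests left both undecided. With both in 1 model, the slope on transcript length was −0.35 (SE 0.036), and between −0.37 and −0.32 in the 9 library pairs. Span alone would leave no such slope, which argues against it for these genes as well. Transcript length alone stays open for them, with a slope on span of −0.040 (SE 0.016). RNA breakage or reverse transcription stops in MGO samples, and a treatment effect on transcription or decay that depends on length, may each contribute and were not tested, because read positions were not analysed here. The labels give an RNA integrity number of 10, without a value per sample.

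The second pattern is the rise of immediate early and snoRNA host genes. With the trend on length, span and GC removed, the median was 2.74 (SE 0.50) for immediate early genes and 1.204 (SE 0.22) for snoRNA hosts, which argues against length as the whole cause of either. Over the scaling alternatives the lower of the 2 medians stayed at 1.49 or above. These alternatives moved the median of all genes by −0.52 to 0.17, which fixed that outcome, so it decides nothing on scaling. A single factor per library moves all genes alike and does not change how far these lists stand above other genes. The MGO treatment itself stays open, and no biological explanation was tested.

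The third pattern is the split of the ISR list, where ATF4, DDIT3 and PPP1R15A rose and ASNS, CHAC1 and SLC7A11 fell. With the length trend removed, 17 of its 20 changed genes kept their call and direction, 10 raised and 7 lowered. Over all genes, 12811 of 17406 calls kept call and direction, so most sets of changed genes would give a similar count. The count shows that the trend does not account for these calls in full, and nothing particular to this list. Log2 fold changes over the 23 tested members had an SD of 2.01 (bootstrap SE 0.27) beside a root mean square SE of 0.14. Scaling by 1 factor per library moves all members alike, so it can neither give nor remove differences between members in any data. The SD is therefore no test of scaling. In 22 of the other 26 lists the SD also lay above 5 times their own such error, so the spread is not particular to this list. How many members rose and fell depends on scaling, with 10 and 10 under library size alone and 13 and 7 under upper quartile scaling. The MGO treatment itself stays open, and no biological explanation was tested, since 1 time point was measured and protein was not analysed here.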
